A study of Homo sapiens with 6 samples.

How the data were processed

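Total RNA from HEK293T cells was hybridised to 6 Affymetrix Human Gene 1.0 ST arrays, 3 from cells transfected with a VRTN plasmid and 3 with the empty vector. Per the labels' protocols, RNA was extracted 24 hours after transfection and 500 ng was used for biotin labelling. The authors deposited log2 values from RMA at default settings, 1 per probe set and array, per the file headers. Affymetrix Expression Console 1.0 is named in the submitters' processing notes. RMA corrects the background, makes the distributions of the arrays equal and summarises the probes, so a shift shared by most transcripts would not show in these values. The genome build was not given in the sources used here. The same values were deposited in a second table, and 0 of the 33297 probe sets differed between the tables.

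The 4114 control probe sets were left out: 2904 negative, 1195 positive, 13 spike and 2 ribosomal RNA controls. Of the 29183 tested, 19460 carried 1 gene symbol, 1752 several and 7971 none in the platform annotation. No gene was named from a probe set with several symbols. The current symbols came from a reference gene table of GRCh38.p14, which was used for names alone. The single-symbol probe sets covered 18417 symbols, 769 of them on more than 1 probe set, and a gene was represented by the probe set with the highest mean over the 6 arrays.

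Groups were compared with limma 3.58.1 in R 4.3.3 by lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. No filter on dim probe sets was applied. A level is compared in the text with the median of the negative control probe sets of the same array, a comparison added after the data were seen. The negative controls spread widely: their 95th percentile was 10.53 to 11.12 in the 6 arrays, and 1.63% to 3.10% of tested probe sets lay above it. Their median is thus not a detection limit, and a level below it does not show that a transcript was absent. Before the data were examined, 30 gene lists were fixed, and 29 with at least 5 measured genes were tested by camera with a preset correlation of 0.01. The list of mitochondrially encoded genes had too few measured members. Members were also adjusted over their own list alone. Gene Ontology terms were not tested, since the annotation used here carries none. Python 3.11.15 with pandas 2.3.3 read the tables and matplotlib 3.10.9 drew the plots.

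The rule for named genes was also fixed before the data were examined. It took up to 10 genes in each direction past the threshold whose groups did not overlap, by size of change, filled up to 10 by the smallest p. It also took up to 2 members of each list in each direction by smallest p, and VRTN, NOTCH1, NOTCH2, JAG1, DLL1, HES1, HEY1 and RBPJ. List members are named in the text for the called lists, for Notch, somite and HOX genes, and for the unfolded protein response and p53 lists. Which lists have members named was chosen after the data were seen.

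Same-numbered arrays deviated together from their group means, with correlations across probe sets of 0.535, 0.157 and 0.499, so the replicate numbers were taken to pair the samples. The first principal component (45.4% of the variance) separated the numbers and the second (19.6%) the groups. Genes are not independent replicates in such a correlation. The limma fit that gave the calls had no block, and the fit with the replicate number as a block is given where it changed a result. The SEs and intervals in the text are those without the block, so they include differences between replicate numbers. The SE was 0.26 without and 0.090 with the block for SLC7A11, and 0.17 and 0.058 for ENO2. It was not smaller with the block for every gene, as for KRT19 (0.100 and 0.105).

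The alternatives were the second table, another quantile normalization, median centring, removal of the dimmest 40 percent, a trended and robust prior, array weights, the replicate block, no moderation, averaged probe sets, fold thresholds of 1.5 and 2, an estimated correlation, fry, and leaving out each array. Leaving out a replicate number in both groups and joining the block to an estimated correlation were added after the data were seen. The 4 lists whose member counts were followed through the alternatives (heat shock, histone, interferon and epithelial) were also chosen after the data were seen. So was the reading of a list's direction. It was first taken from camera alone, then, after the turned lists had been seen, from the sign of the median, and at last a list was counted as turned when either turned. The closing section gives the counts of all 3 readings.

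The fits were tested on simulated data made for the comparison of VRTN with empty vector, on 29183 probe sets with 200 changed per run and 5 runs. Where each probe set kept its own estimated spread, the fit without the block called 54.9% of changes of 1.5-fold, 94.6% of 2-fold and 99.1% of 3-fold, and 0.1% of calls were false. Where spreads were drawn from the fitted prior, it called 35.5%, 87.5% and 98.5%, with 0.5% false. The fit with the replicate block called more, 98.2% of changes of 1.5-fold in the former and 74.9% in the latter. Of its calls 11.3% were false in the former, above the share the adjusted p threshold allows, and 4.4% in the latter, below that share. Both lay above the shares without the block, so the blocked counts are less certain than the unblocked ones. Whether the blocked fit exceeds the threshold in the real data is not settled, since the simulated answer changed with the spreads. Without the block the false shares lay well below the threshold, so that fit was stricter than the threshold asks in these simulations. A simulated list of 30 genes shifted by 0.3 was called in 5 of 5 runs under both kinds of spread, by camera with the preset and with an estimated correlation. Camera with the preset also called 0 of 95 unshifted lists in the former and 1 of 95 in the latter. The simulated noise is independent between genes and the lists are random, so this says nothing of lists whose members are correlated.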

Results

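Gene expression was measured in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. The cells had been transfected with a plasmid that expresses flag-tagged pig VRTN, or with the same plasmid without an insert. VRTN (vertnin) is a DNA-binding protein whose gene has been associated with the number of vertebrae in pigs. There were 3 arrays per group, which the labels call biological replicates, and total RNA was taken 24 hours after transfection. Each array gave a log2 signal for 33297 probe sets, of which 29183 were not controls and were tested. The median log2 signal of these lay between 6.43 and 6.47 in the 6 arrays. With 3 arrays per group, the number of arrays limits the precision of each value.

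The comparison asked which transcripts differed in cells given the VRTN plasmid. The probe set for human VRTN was higher after transfection, at 6.18 ± 0.10 (SD, n = 3) against 5.10 ± 0.11 (SD, n = 3) with the empty vector. Its log2 fold change was 1.07 (SE 0.086, 95% interval 0.88 to 1.27; limma adjusted p = 0.0194), and all 3 VRTN arrays lay above all 3 control arrays. The plasmid holds the pig coding sequence, and how well the human probes bind it was not measured. The VRTN level lay below the median of the negative control probe sets, 5.36 to 6.13 in the 6 arrays, in all 3 control arrays and above it in all 3 VRTN arrays. In VRTN replicate 3 the 2 were nearly equal, at 6.068 against 6.063. The size of the VRTN change is therefore uncertain. The VRTN call was lost without the variance moderation of limma (adjusted p = 0.554). It was also lost without VRTN replicate 1 (0.131), 2 (0.264) or 3 (0.0527) and without empty vector replicate 2 (0.189) or 3 (0.154), while the log2 fold change stayed between 1.01 and 1.13.

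Of the 29183 probe sets, 4 passed an adjusted p of 0.05 and all 4 were higher with VRTN. Besides VRTN they were DNAJB1, HSPH1 and probe set 8057613, which the annotation used here does not name. DNAJB1, a co-chaperone of HSP70, rose by 1.54 on the log2 scale (SE 0.12, n = 3 per group; adjusted p = 0.0182). HSPH1, a large chaperone of the HSP70 family, rose by 0.96 (SE 0.087; adjusted p = 0.0374). Probe set 8057613 rose by 1.68 (SE 0.079; adjusted p = 0.00102), from 9.10 ± 0.09 to 10.78 ± 0.08 (SD, n = 3). With the replicate number as a replicate block 8 probe sets passed, all higher. The added ones were the collagen chaperone SERPINH1 (1.20), the secreted chaperone CLU (1.06), the arsenite-inducible zinc finger gene ZFAND2A (1.16) and the unnamed probe set 8095744 (1.34), each at adjusted p = 0.0434. Probe set 8095744 lay below the negative control median in all 6 arrays. For each gene and probe set named here, all 3 VRTN arrays lay above all 3 control arrays. CLU lies outside the rule for named genes and was chosen after its value was seen. The 4 calls fell to 1 without VRTN replicate 1, VRTN replicate 2, empty vector replicate 2 or empty vector replicate 3, and to 2 without VRTN replicate 3. DNAJB1 lost its call without VRTN replicate 1 (adjusted p = 0.125) or 2 (0.0715) and without empty vector replicate 2 (0.189) or 3 (0.154), while its log2 fold change stayed between 1.43 and 1.62 without single arrays. HSPH1 lost its call without VRTN replicate 1 (0.228), 2 (0.396) or 3 (0.119), without empty vector replicate 2 (0.370) or 3 (0.195), and after another quantile normalization (0.0578), with log2 fold changes of 0.90 to 1.04 without single arrays. Both lost it without the variance moderation (adjusted p = 0.554).

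No probe set fell past the threshold in limma, and 3 did with array weights. At an unadjusted p under 0.05, 1627 probe sets stood apart, 774 higher and 853 lower, where chance gives about 1459. There were 3357 with the replicate number as a replicate block, 1550 higher and 1807 lower. The groups did not overlap for 11.3% of probe sets, where chance gives 10% if the arrays are not paired. All 12 probe sets that differed by at least 2-fold were higher with VRTN. The lower genes with the smallest p and groups that did not overlap were not past the threshold. Among them, the log2 fold change was -0.57 (SE 0.073; adjusted p = 0.231) for KITLG, the ligand of the receptor KIT. It was -0.50 (SE 0.066; adjusted p = 0.238) for FBXW7, a ubiquitin ligase subunit that targets Notch and cyclin E. The others were LRIG3 (-0.48), MTERF3 (-0.42), SEMA3C (-0.50), ZNF214 (-0.53), H3C10 (-0.52), H3C7 (-0.48), BCHE (-0.37) and CCDC50 (-0.35). The higher genes named by the same rule that did not pass were ZFAND2A, SERPINH1, KRT8 (1.06), TSPYL2 (0.63), CRYAB (1.57), EMP3 (0.50) and CST4 (0.70). With array weights ZFAND2A, SERPINH1, KRT8, CRYAB and FBXW7 passed at adjusted p = 0.0455, and KITLG and CLU at 0.0474. BCHE lay below the negative control median in all 6 arrays.

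Heat shock protein genes, which encode chaperones, had the highest median change of the 29 gene lists tested. Of 24 measured members, 12 rose when adjusted over the list alone, 2 of them also over all probe sets (DNAJB1 and HSPH1), and none fell. CRYAB, a small heat shock protein, rose by 1.57 (SE 0.22, n = 3 per group; adjusted p = 0.00091, adjusted over the list alone). It lay below the negative control median in all 3 control arrays and in 2 of the 3 VRTN arrays, so the size of its change is uncertain. The stress-inducible HSPA6 rose by 1.48 (SE 0.27) and HSPB8, another small heat shock protein, by 1.15 (SE 0.20). HSPA8, a constitutive member of the HSP70 family, rose by 0.23 (SE 0.077) and HSP90AA1, the stress-inducible HSP90, by 0.22 (SE 0.068). HSF1, the transcription factor of the heat shock response, had a log2 fold change of -0.091 (SE 0.097) and DNAJB4 of -0.071 (SE 0.071), neither past the test. HSPA6, HSPB8, HSPA8 and HSP90AA1 lie outside the rule for named genes and were chosen after their values were seen. The median over the list was 0.22, and 0.19, 0.29 and 0.20 in the 3 same-numbered pairs. The list was called higher by camera with a preset correlation (adjusted p = 1.15e-18). The call was lost with its own correlation, at adjusted p = 0.580 with an estimated correlation. Other splits of the 6 arrays into 3 and 3 called up to 14 lists by camera, against 10 in the real split. For this and the lists below, a camera call alone therefore does not set VRTN apart from other groupings. With the replicate number as a replicate block 16 members rose and 0 fell, adjusted over the list alone. The 12 calls fell to 9 without the variance moderation and to 7 without VRTN replicate 1, VRTN replicate 2 or empty vector replicate 2. The hybridisation spikes described next were also higher, by 0.35, in the VRTN arrays.

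**Figure D1:**
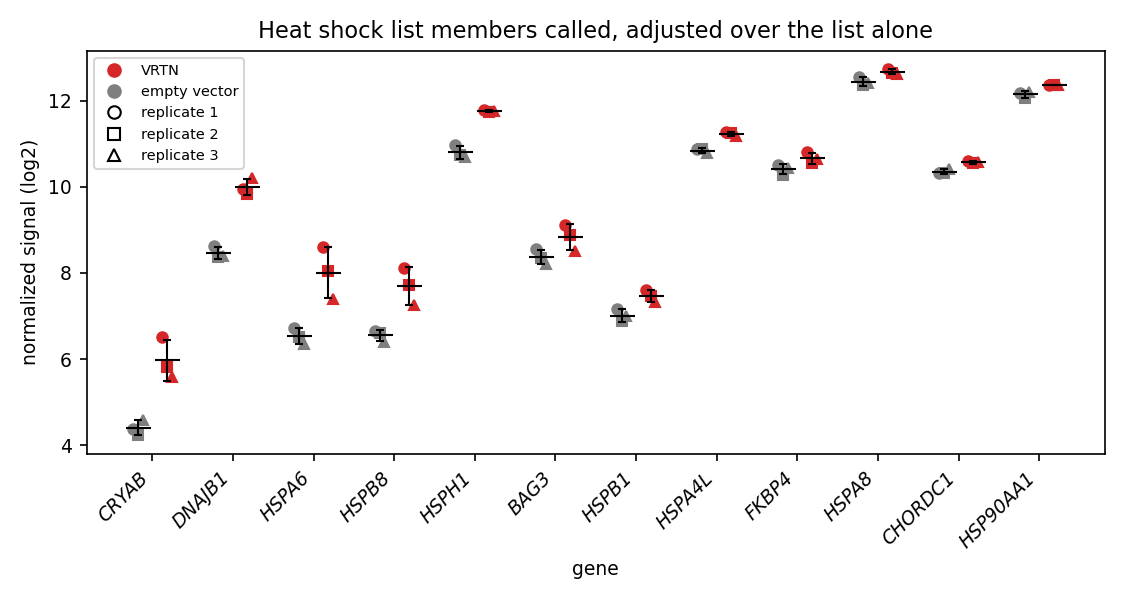
Normalized log2 signal (vertical axis) of the 12 heat shock genes called when adjusted over the list alone (horizontal axis), by array, with VRTN in red, the empty vector in grey, marker shapes for the replicate number, and bars for the mean and SD of 3 arrays. DNAJB1 rose from 8.46 to 9.99 and HSPH1 from 10.80 to 11.75, while CRYAB, at 4.40 with the empty vector, lay below the negative control median of all 3 control arrays.

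The control spikes gave a measured difference between the groups that stands beside each gene group here, but a link between them was not tested. In limma on the control probe sets alone, 0 of the 13 spike probe sets passed and 4 were higher at an unadjusted p under 0.05. Spike probe sets of the same array are not independent replicates. The 9 probe sets for bacterial hybridisation spikes were on average 0.35 higher on the log2 scale in the VRTN arrays, at 10.60 ± 0.10 against 10.24 ± 0.19 (SD, n = 3). All 3 VRTN means lay above all 3 control means (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). The 4 probe sets for poly(A) spikes differed by -0.045, at 9.73 ± 0.07 against 9.78 ± 0.12 (exact permutation p = 0.7).

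**Figure D2:**
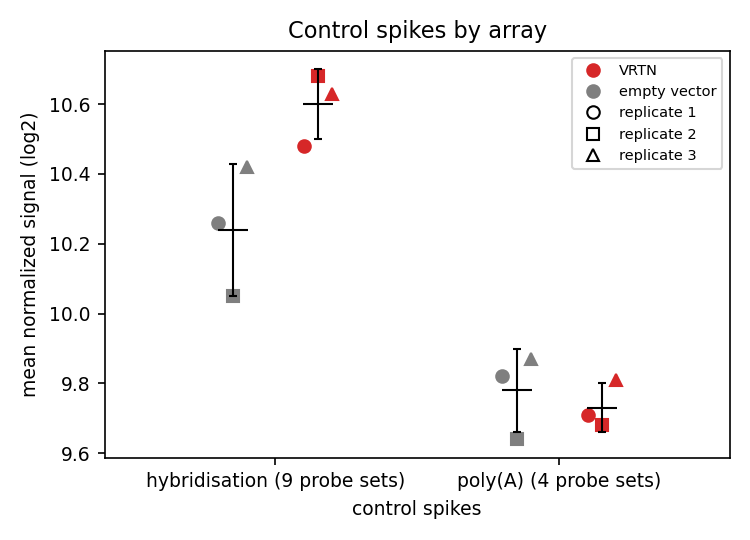
Mean normalized log2 signal (vertical axis) of 9 hybridisation and 4 poly(A) spike probe sets (horizontal axis) in each array, with VRTN in red, the empty vector in grey, marker shapes for the replicate number, and bars for the mean and SD of 3 arrays. The hybridisation spikes lay between 10.48 and 10.68 in VRTN arrays and between 10.05 and 10.42 in control arrays.

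Replication-dependent histone genes were lower with VRTN. Of 60 measured members, 7 fell when adjusted over the list alone, 0 passed over all probe sets in limma, and none rose. At an unadjusted p under 0.05, 17 were lower and 0 higher. H3C10 fell by 0.52 on the log2 scale (SE 0.093, n = 3 per group) and H3C7 fell by 0.48 (SE 0.088), both at adjusted p = 0.0188, adjusted over the list alone. On the higher side H1-6 (0.22) and H2AC14 (0.084) had the smallest p and did not pass, and they lay below the negative control median in 4 and 6 arrays. The median over the list was -0.15, and -0.19, -0.12 and -0.15 in the same-numbered pairs. Camera called the list lower (adjusted p = 4.52e-12), and the call was lost at adjusted p = 0.616 with an estimated correlation. With the replicate number as a replicate block 23 members fell, with array weights 15 and without the variance moderation 2. With each array left out in turn, 0 to 2 members fell: 0 without VRTN replicate 1, VRTN replicate 2 or empty vector replicate 2, 1 without VRTN replicate 3 or empty vector replicate 1, and 2 without empty vector replicate 3. Histone genes are near-identical copies of one another and can share probes. The hybridisation spikes were 0.35 higher in the VRTN arrays.

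Genes of the G1/S transition were lower as a group without any member passing. Of 43 measured members 37 had a negative log2 fold change and 0 passed when adjusted over the list alone or over all probe sets in limma. At an unadjusted p under 0.05, 8 were lower and 0 higher. The DNA helicase BLM had a log2 fold change of -0.33 (SE 0.11, n = 3 per group) and the phosphatase CDC25A of -0.24 (SE 0.076). On the higher side UHRF1 (0.051) and CCNE1 (0.029) had the smallest p and did not pass, and a second UHRF1 probe set was at 0.0027. Without VRTN replicate 1 both turned negative (UHRF1 -0.050, CCNE1 -0.042), as they did without empty vector replicate 3 (-0.069 and -0.010). CCNE1 was also negative without VRTN replicate 2 (-0.0042) or empty vector replicate 2 (-0.0035). The median was -0.10. It was -0.063 without VRTN replicate 3, -0.16 without VRTN replicate 1 and -0.16 without empty vector replicate 3. Camera called the list lower (adjusted p = 2.39e-07), which was lost at adjusted p = 0.825 with an estimated correlation. Genes of G2/M were not called (adjusted p = 0.512), and their median over 50 genes was -0.00090. They were called higher after another quantile normalization (median 0.030; adjusted p = 0.0452) and without empty vector replicate 3 (median 0.026; adjusted p = 0.0303). The hybridisation spikes were 0.35 higher in the arrays where the G1/S genes were lower.

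Interferon-stimulated genes were higher with VRTN. Of 51 measured members, 5 rose when adjusted over the list alone and 0 over all probe sets in limma. At an unadjusted p under 0.05, 11 were higher and 1 lower. IRF9, a subunit of the interferon-activated factor ISGF3, rose by 0.60 (SE 0.11, n = 3 per group) and IFI44L by 0.90 (SE 0.18), both at adjusted p = 0.0253, adjusted over the list alone. The other 3, chosen after their values were seen, were BST2 (0.41), HERC6 (0.37) and IFIT2 (0.63). BST2, IFIT2 and CXCL11 lay below the negative control median in all 6 arrays and IFI44L in 3, so the sizes of their differences are uncertain. USP18 (-0.21) and CXCL11 (-0.14) did not pass. The median was 0.10, and camera called the list higher (adjusted p = 2.27e-07), lost at adjusted p = 0.825 with an estimated correlation. The median was 0.067 without VRTN replicate 1 and 0.066 without empty vector replicate 3. With the replicate number as a replicate block 11 rose and 1 fell. With array weights 9 rose, without the dimmest 40 percent of probe sets 2 and without the variance moderation 0. Without VRTN replicate 2, empty vector replicate 2 or empty vector replicate 3 no member passed, without VRTN replicate 1 there were 2, and without VRTN replicate 3 there were 8. The hybridisation spikes were higher in the same arrays, by 0.35.

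Among 16 measured epithelial and keratin markers, 2 rose when adjusted over the list alone and 0 over all probe sets in limma. At an unadjusted p under 0.05, 5 were higher and 0 lower. KRT8, a keratin of simple epithelia, rose by 1.06 (SE 0.14, n = 3 per group; adjusted p = 0.00114, adjusted over the list alone). EPCAM, an epithelial adhesion molecule, rose by 0.56 (SE 0.14; adjusted p = 0.0322 over the list alone), and lay below the negative control median in 4 of the 6 arrays. A second EPCAM probe set was at 0.98, from 4.88 to 5.85. KRT19 was at -0.077 and CLDN7 at -0.053, neither past the test. CLDN7 lay below the negative control median in 5 of the 6 arrays, and KRT19 turned to 0.0032 without VRTN replicate 1. Camera called the list higher (adjusted p = 0.0083; median 0.032), lost at adjusted p = 0.616 with an estimated correlation and at 0.0508 with array weights (median 0.010). The median was 0.11 without the dimmest 40 percent of probe sets and 0.058 with probe sets averaged. The median of 0.032, with all probe sets, lay inside the central 95% range of 10000 random lists matched on level (-0.054 to 0.058). With the replicate number as a replicate block 4 rose, and 1 rose without VRTN replicate 2, empty vector replicate 2 or empty vector replicate 3. Without empty vector replicate 3 the median was -0.00042, while camera still called the list higher (adjusted p = 0.0485). It was 0.072 without VRTN replicate 2, 0.055 without empty vector replicate 1 and 0.052 without empty vector replicate 2. The hybridisation spikes were 0.35 higher in the same arrays.

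The Notch pathway, which patterns the somites that form vertebrae, gave no call. Of 59 measured members 0 passed, adjusted over the list alone or over all probe sets in limma, and 1 was higher at an unadjusted p under 0.05. That gene was NOTCH1, with a log2 fold change of 0.26 (SE 0.084, 95% interval 0.06 to 0.45, n = 3 per group; adjusted p = 0.802). The target genes HEY1 (-0.23, SE 0.15), HES1 (-0.16, SE 0.20), HES4 (-0.20, SE 0.10) and HEY2 (-0.17, SE 0.095) did not pass. HEY1, HES1 and HES4 were lower in all 3 same-numbered pairs, and HEY2 was not. With the replicate block the unadjusted limma p was 0.026 for HEY1, 0.037 for HES1, 0.020 for HES4, 0.070 for HEY2 and 0.0093 for NOTCH1. None of these passed with the block over the list alone or over all probe sets (adjusted p over all probe sets 0.308 to 0.465). The receptor NOTCH2 (-0.067), the ligands JAG1 (0.066) and DLL1 (-0.059), the DNA-binding protein RBPJ (0.011) and the coactivator EP300 (0.15) did not pass either. The sign of RBPJ turned with array weights (-0.011), with its probe sets averaged (-0.063), and without VRTN replicate 3 (-0.094) or empty vector replicate 1 (-0.11). That of HES1 turned without empty vector replicate 3 (0.0069), a setting that left the replicate numbers unbalanced between the groups. The median over the list was 0.0034 and its mean -0.0034, and camera gave adjusted p = 0.604. The median was -0.0019 with each array centred on its median, -0.0064 with array weights, -0.0092 without VRTN replicate 1 and -0.0040 without empty vector replicate 3.

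Somite and axis genes were not called (49 measured, 0 passed in limma over the list alone or over all probe sets, 2 lower at an unadjusted p under 0.05; median -0.021; camera adjusted p = 0.350). The median of the somite list varied between the same-numbered pairs, at -0.094, -0.040 and -0.0010. EFNB2 (-0.25, SE 0.078, n = 3 per group) and LIN28B (-0.22, SE 0.079) had the smallest p on the lower side, RIPPLY1 (0.16) and GDF11 (0.14) on the higher. HOX genes were not called (27 measured, 0 passed in limma over the list alone or over all probe sets, 1 higher at an unadjusted p under 0.05; adjusted p = 0.700). HOXD12 was at 0.26 (SE 0.097), HOXB2 at 0.24 (SE 0.10), HOXB13 at -0.15 (SE 0.068) and HOXC5 at -0.14 (SE 0.081). HOXD12 lay below the negative control median in all 6 arrays and RIPPLY1 in 4. The median of the HOX list was -0.016, while its mean was 0.011 and camera pointed up. The median turned without VRTN replicate 1 (0.00047) or 2 (0.014) and without empty vector replicate 2 (0.0046) or 3 (0.018), and camera's direction without empty vector replicate 1 (median -0.030).

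The 5 other called lists had no member past the test, over the list alone or over all probe sets, in limma. At an unadjusted p under 0.05, 2 amino acid response genes were lower, 0 oxidative phosphorylation genes stood apart, and 2 chromatin, 2 hypoxia and 4 immediate early genes were higher. Genes of the amino acid response under ATF4 were lower (32 genes, median -0.082; adjusted p = 0.00777, and adjusted p = 0.825 with an estimated correlation). The cystine transporter gene SLC7A11 was at -0.64 (SE 0.26) there, EPRS1 at -0.18 (SE 0.066), SLC38A2 at 0.13 and CEBPB at 0.074, which was -0.024 without VRTN replicate 1. Nuclear genes of oxidative phosphorylation were lower (65 genes, median -0.052; adjusted p = 0.0141, and adjusted p = 0.825 with an estimated correlation), with NDUFB7 at -0.20, COX6C at -0.16, UQCRC2 at 0.058 and NDUFS1 at 0.049. Chromatin regulators were higher (48 genes, median 0.038; adjusted p = 0.0329, and adjusted p = 0.825 with an estimated correlation), with TET3 at 0.21, CHD8 at 0.18, SETDB2 at -0.19 and HDAC4 at -0.13. Hypoxia and glycolysis genes were higher (29 genes, median 0.041; adjusted p = 0.0329, and adjusted p = 0.833 with an estimated correlation), with ENO2 at 0.56, P4HA2 at 0.25, PFKP at -0.086 and HK1 at -0.071. Immediate early genes were higher (30 genes, median 0.028; adjusted p = 0.0427, and adjusted p = 0.825 with an estimated correlation), with NR4A1 at 0.22, ZFP36 at 0.35, ATF3 at -0.24 and KLF6 at -0.16. With the replicate number as a replicate block 8 hypoxia genes passed when adjusted over the list alone, 7 of them higher, and SLC7A11 fell (adjusted p = 0.0133, adjusted over the list alone). The hybridisation spikes were 0.35 higher in the arrays where these lists differed.

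The calls of these 5 lists depended on which arrays were kept. Leaving out 1 array also leaves the replicate numbers unbalanced between the groups, so these losses are not separated from the differences between replicate numbers. Leaving out a replicate number in both groups, which keeps the balance, also ended calls of the chromatin, immediate early, hypoxia and oxidative phosphorylation lists. The amino acid response lost its call without VRTN replicate 3 (adjusted p = 0.321) or empty vector replicate 2 (0.171). Oxidative phosphorylation lost it without VRTN replicate 2 (0.238) or 3 (0.0994) and without empty vector replicate 1 (0.692) or 3 (0.143), and after another quantile normalization (0.208). Chromatin regulators lost it without VRTN replicate 2 (0.0633) or 3 (0.556) or empty vector replicate 1 (0.826). Hypoxia genes lost it without VRTN replicate 2 (0.0815) or 3 (0.996) or empty vector replicate 1 (0.826), and in the last 2 of these their median turned, to -0.023 and -0.025. Immediate early genes lost it without VRTN replicate 2 (0.162) or 3 (0.157) and without empty vector replicate 1 (0.679) or 3 (0.0632). Array weights also ended the calls of oxidative phosphorylation (0.0801), chromatin (0.210), hypoxia (0.0616) and immediate early genes (0.187).

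Single arrays also moved these medians by more than 1.5 times. The amino acid response median was -0.051 without empty vector replicate 2 and -0.13 without empty vector replicate 3. That of oxidative phosphorylation was -0.086 without VRTN replicate 1, -0.018 without empty vector replicate 1 and -0.097 without empty vector replicate 2. The chromatin median was 0.020 without VRTN replicate 3 and 0.012 without empty vector replicate 1. That of hypoxia was 0.19 without VRTN replicate 1, 0.0098 without VRTN replicate 2 and 0.14 without empty vector replicate 3. The immediate early median was 0.073 without VRTN replicate 1, 0.063 without VRTN replicate 3, 0.075 without empty vector replicate 2 and 0.0095 without empty vector replicate 3.

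In all, 10 of the 29 lists tested were called by camera, 6 higher and 4 lower. Of the 10 splits of the 6 arrays into 3 and 3, 5 called at least as many lists, the real one included. The number of list calls thus does not tell the VRTN grouping from other groupings. No list was called with an estimated correlation, where 1 had an unadjusted p under 0.05, and none by fry, where 2 did. Fry asks whether a list moves one way on balance. By the mixed form of fry, which asks whether members change in either direction, 3 lists passed: heat shock (adjusted p = 0.00626), histones (0.0106) and epithelial markers (0.0173). With the replicate number as a replicate block 12 lists were called, the added ones being small nucleolar RNAs (adjusted p = 0.00865) and zinc finger genes (0.0274), and 0 were called when the block was joined to an estimated correlation. For 8 lists, chosen after the data were seen, the median was set against those of 10000 random lists matched on level. The heat shock and interferon medians lay above the central 95% range of the random lists, those of histones and G1/S genes below it, and those of epithelial markers, Notch, somite and HOX genes inside it.

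**Figure D3:**
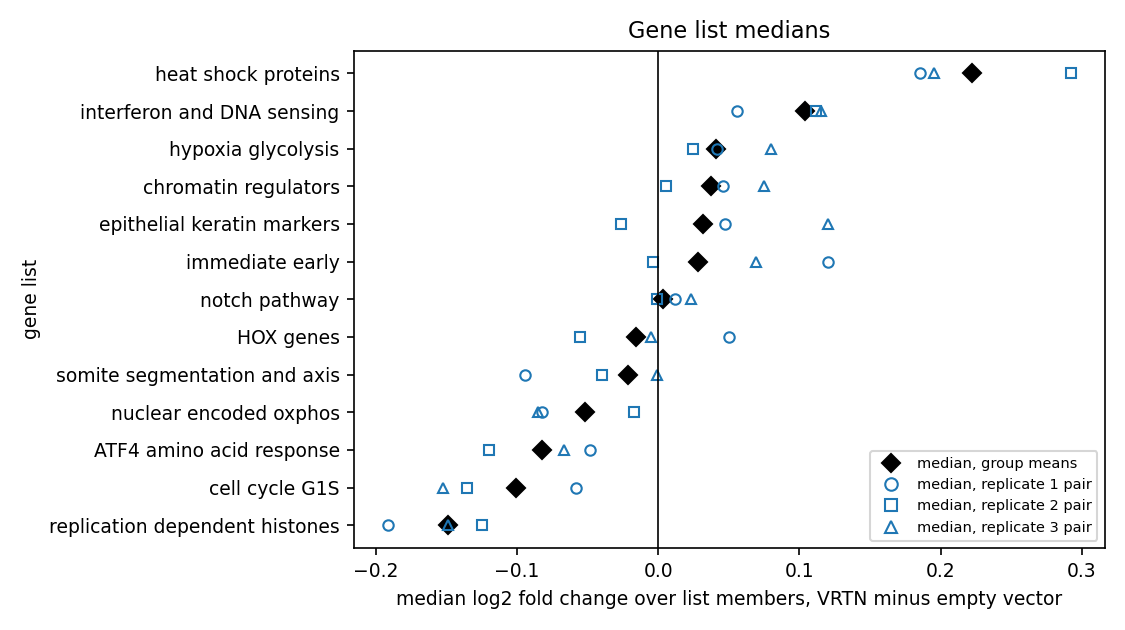
Median log2 fold change over list members, VRTN minus empty vector (horizontal axis), for the 10 called lists and the Notch, somite and HOX lists (vertical axis), with diamonds for the median from group means and open symbols for the median in each same-numbered pair. The heat shock median of 0.22 was the highest and the histone median of -0.15 the lowest, and the Notch median of 0.0034 was -0.0019 with each array centred on its median.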

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

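The test of the hybridisation spikes against the poly(A) spikes was chosen after the spikes had been seen. Control spikes are outside the main measurement, and the mean of 1 kind differed between the groups, while 0 of the 13 spike probe sets passed in limma. The 9 hybridisation spikes were higher in VRTN arrays by 0.35 on the log2 scale, with 8 of the 9 higher in all 3 VRTN arrays than in any control array. RMA makes the distributions of the arrays equal, so a shift of all bright probe sets would be taken out of these values and was not tested. The poly(A) spikes, added to the RNA before amplification, differed by -0.045, which argues against less RNA entering amplification in the VRTN samples. A difference in hybridisation or in the amount of spike added may remain, and with group and spike moving together in all 3 pairs it was not separated from the effect of VRTN.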

How the results depend on the processing

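Leaving out a replicate number in both groups, joining the block to an estimated correlation, the choice of 4 lists for member counts and the reading of list directions came after the data were seen. Of the 609 values of lists under an alternative, the median turned in 52, the direction of the set test in 36 and either in 76. The second table, the prior, moderation, the block and the set test cannot move a median. Over the 406 values that leaves, the median turned in 52, the set test in 29 and either in 69, of which 3 belonged to called lists (140 values). Those 3 came from leaving out a single array. With all arrays kept or a replicate number left out of both groups, 0 of 150 values of called lists turned, settings that cannot move a median included. Leaving out the identical second table, values of named genes other than VRTN passed the threshold in 10 cases, turned in 16 and lost it in 18, all 18 of them DNAJB1 or HSPH1. The remaining 1440 were mostly of genes that were not called, and say little of stability. Scaling moved the median of all probe sets from -0.0049 to -0.0013 or -0.010. The cause of the changes below was not tested, except that settings without an array hold fewer samples. Settings without a single array also leave the replicate numbers unbalanced between the groups. VRTN had no value without the dimmest probe sets, since its own level is among them. In each array, 54.8% to 67.3% of the tested probe sets lay above the median of the negative controls, so small changes of dim probe sets are less certain. That median is not a detection limit, since the negative controls spread widely.

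The 4 probe sets called became 14 with array weights (11 higher and 3 lower), 8 with the replicate block, 0 without moderation, 12 at an unadjusted p with a 2-fold change, and 1 to 4 without single arrays. Without replicate 1, 2 or 3 of both groups they were 1, 0 and 0. VRTN kept a log2 fold change of 1.07 without moderation but not its call, with 1.01 to 1.13 without single arrays, and 1.09, 0.99 and 1.15 without replicate 1, 2 and 3 of both groups. The 12 heat shock members were 16 with the replicate block, 7 to 12 without single arrays and 6 without replicate 2 of both groups. The 7 histone members were 15 with array weights, 23 with the replicate block, 2 without moderation, 0 to 2 without single arrays, and 0, 0 and 1 without replicate 1, 2 and 3 of both groups. The 5 interferon members were 2 without the dimmest probe sets, 9 with array weights, 11 with the replicate block, 0 without moderation, 0 to 8 without single arrays, and 3, 0 and 3 without replicate 1, 2 and 3 of both groups. The 2 epithelial members were 4 without the dimmest probe sets, with array weights or with the replicate block, 1 to 3 without single arrays, and 1 without replicate 2 or 3 of both groups.

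The 10 lists called became 5 with array weights, 0 with an estimated correlation, 0 with fry, 0 with the replicate block and an estimated correlation, and 6 without replicate 3 of both groups. In those with no list called the medians stayed as they were, since only the test changed: heat shock 0.22, interferon 0.10, hypoxia 0.041, chromatin 0.038, epithelial 0.032, immediate early 0.028, oxidative phosphorylation -0.052, amino acid response -0.082, G1/S -0.10 and histone -0.15. The unfolded protein response list (-0.0071) also turned by fry, as did it, endothelial and liver (-0.013) and neuronal (-0.016) with the block and an estimated correlation.

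The values in parentheses are list medians of the log2 fold change. A list is given as turned when its median or the direction of the set test turned. A printed median need not have changed its sign. After another quantile normalization, the direction turned for the lists G2/M (0.030) and unfolded protein response (0.029). The call was lost for oxidative phosphorylation (-0.028) under that setting. A call was gained for zinc finger (-0.033) and, in its turned direction, G2/M under that setting. With each array centred on its median, the direction turned for the lists Notch (-0.0019) and p53 (-0.0037). Without the dimmest 40 percent of probe sets, the direction turned for the lists neuronal (0.030) and p53 (-0.0056). A call was gained for small nucleolar RNA (-0.085) under that setting. With a trended, robust prior, a call was gained for ribosomal protein (-0.028) and small nucleolar RNA (-0.060). With array weights, the direction turned for the lists G2/M (0.019), endothelial and liver (0.023), HOX (-0.038), neuronal (-0.0097), Notch (-0.0064), p53 (-0.027) and unfolded protein response (0.019). Of these, HOX and neuronal turned in the set test alone and not in the median. The call was lost for chromatin (0.028), epithelial (0.010), hypoxia (0.026), immediate early (0.012) and oxidative phosphorylation (-0.040) under that setting. With the replicate block, the direction of the set test alone turned for the lists endothelial and liver (-0.013), neuronal (-0.016) and unfolded protein response (-0.0071). A call was gained for small nucleolar RNA (-0.060) and zinc finger (-0.037) under that setting. With the probe sets of a gene averaged, the direction turned for the neuronal list (0.0045). A call was gained for small nucleolar RNA (-0.060) under that setting. Without replicate 1 of both groups, the direction turned for the lists blood cell (-0.0099), G2/M (0.013), endothelial and liver (0.040), HOX (-0.051), neuronal (0.025), p53 (-0.050) and unfolded protein response (-0.021). The call was lost for chromatin (0.042) and immediate early (0.030) under that setting. A call was gained for olfactory receptor (0.043), skeletal (0.070), small nucleolar RNA (-0.037) and zinc finger (-0.062) under that setting. Without replicate 2 of both groups, the direction turned for the lists G2/M (-0.014), HOX (0.023), neuronal (0.0093), TGF-beta and BMP (0.019) and unfolded protein response (0.00062). The call was lost for hypoxia (0.052) under that setting. A call was gained for ribosomal protein (-0.041) and small nucleolar RNA (-0.071) under that setting. Without replicate 3 of both groups, the direction turned for the lists G2/M (0.0085), olfactory receptor (-0.013), p53 (-0.013) and unfolded protein response (0.034). The call was lost for chromatin (0.034), epithelial (0.00038), immediate early (0.019) and oxidative phosphorylation (-0.034) under that setting.

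Without single arrays, the medians of most lists with a change in call, direction or size ranged as follows. No range is given here for the heat shock, histone, somite and cholesterol lists. The ranges were G1/S (-0.16 to -0.063), interferon (0.066 to 0.15), amino acid response (-0.13 to -0.051), blood cell (-0.070 to 0.014), G2/M (-0.0047 to 0.026), chromatin (0.012 to 0.056), ribosomal protein (-0.062 to 0.0012), endothelial/liver (-0.081 to 0.011), epithelial (-0.00042 to 0.072) and fibroblast (0.023 to 0.060). Further ranges were HOX (-0.030 to 0.018), hypoxia (-0.025 to 0.19), immediate early (0.0095 to 0.075), neuronal (-0.055 to -0.0020), NF-kB (-0.0011 to 0.074), Notch (-0.0092 to 0.013), oxidative phosphorylation (-0.097 to -0.018) and olfactory receptor (-0.0071 to 0.041). The last were p53 (-0.11 to 0.053), skeletal (0.022 to 0.066), small nucleolar RNA (-0.092 to -0.030), TGF-beta/BMP (-0.038 to 0.0075), unfolded protein response (-0.027 to 0.046), Wnt (-0.12 to 0.022) and zinc finger (-0.060 to -0.00025). Among genes, RBPJ was -0.011 with array weights, -0.063 with probe sets averaged, -0.0095 without replicate 1 of both groups and -0.11 to 0.13 without single arrays. KRT19 was 0.056 without replicate 1 of both groups and -0.15 to 0.0032 without single arrays, and HES1 was -0.36 to 0.0069. UHRF1 was -0.069 to 0.18 without single arrays, and CCNE1 was -0.042 to 0.13 and, without replicate 2 of both groups, -0.037. CEBPB was -0.024 to 0.13 without single arrays. Further medians that moved by more than 1.5 times included amino acid response (-0.052), chromatin (0.062), hypoxia (0.070), HOX (-0.0051), Notch (0.015) and somite (-0.0090) after another quantile normalization. Under that setting ribosomal protein (-0.0020), cholesterol (-0.016), p53 (0.022), olfactory receptor (0.0055), endothelial and liver (-0.024), TGF-beta and BMP (-0.012) and neuronal (-0.026) medians also moved by more than 1.5 times. The epithelial median did so without the dimmest probe sets (0.11) and with probe sets averaged (0.058), and Notch under the same settings (0.0021 and 0.00081). Without single arrays, calls were also gained in the turned direction for G2/M (0.026) and p53 (-0.11 and -0.095), and lost for hypoxia where it turned (-0.023 and -0.025).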

Other observations

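The tests below of gene families, the unfolded protein response, small nucleolar RNAs and G1/S genes were chosen after the values were seen. Lists that were not called add the following values. The unfolded protein response list, which follows stress in the endoplasmic reticulum, had a median of -0.0071 over 25 genes and adjusted p = 0.915, with DDIT3 at 0.34 (SE 0.097, n = 3 per group), DNAJB9 at 0.11, XBP1 at -0.24 (SE 0.085) and ATF6 at -0.20. Its mean was also negative while camera pointed up, and its median was 0.029 after another quantile normalization. Targets of p53 had a median of 0.0016, a mean of -0.034, a median of -0.0037 with each array centred on its median, and adjusted p = 0.452, with PMAIP1 at -0.31, GADD45A at -0.37, TP53INP1 at 0.26 and CDKN1A at 0.21. The p53 list was called lower without VRTN replicate 1 (median -0.11; adjusted p = 0.0258) and without empty vector replicate 3 (median -0.095; adjusted p = 0.0485). PMAIP1 and GADD45A fell, adjusted over the list alone, with the replicate number as a replicate block. Targets of TGF-beta and BMP (adjusted p = 0.604), Wnt (0.414), NF-kB (0.18) and cholesterol synthesis (0.286) were not called. Ribosomal proteins (0.110), small nucleolar RNAs (0.0548), zinc finger genes (0.0574) and olfactory receptors (0.0627) were not called. Ribosomal proteins were called lower without VRTN replicate 3 (0.000746) or empty vector replicate 2 (0.000897), and small nucleolar RNAs without VRTN replicate 3 (0.00144) or empty vector replicate 1 (0.0181) or 2 (0.000102). Zinc finger genes were called lower without VRTN replicate 1 (0.00104) or 2 (0.0198) or empty vector replicate 1 (0.0181). Olfactory receptors were called higher without VRTN replicate 1 (0.0143) or empty vector replicate 1 (0.0209). The G2/M list had a median of -0.00090 and a mean of 0.0090, and was called higher after another quantile normalization (median 0.030; adjusted p = 0.0452) and without empty vector replicate 3 (0.0303).

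Markers of other tissues were not called: skeletal and cartilage (adjusted p = 0.0574), fibroblast (0.198), blood (0.842), neuronal (0.915) and endothelial and liver (0.963). Skeletal (0.0193) and fibroblast markers (0.0465) were called higher without VRTN replicate 1. With the replicate block 1 neuronal marker and 1 endothelial or liver marker rose, adjusted over the list alone, where 0 did without the block. The neuronal marker was ENO2, which is also a member of the hypoxia and glycolysis list. The neuronal median was -0.016 and its mean 0.012, while camera pointed down, and the endothelial and liver median was -0.013 with a mean of 0.00098 and camera pointing down.

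A hypothesis is that the VRTN cells had a heat shock response. The calls lay in 7 gene families, which argues against shared probes as the whole source. The unfolded protein response mean had an upper bound of 0.048 over list members, below the heat shock mean of 0.43. This bound takes genes as independent and leaves out the spread between arrays, so it does not decide on its own. In the same-numbered pairs the unfolded protein response medians were 0.041, 0.022 and -0.044, below heat shock medians of 0.19, 0.29 and 0.20. These medians argue against stress of the endoplasmic reticulum as the whole source. RMA makes the distributions of the arrays equal, so random lists matched on level do not test a bias that follows signal level. A difference in hybridisation or handling between the groups may account for it, and no plasmid with another protein was there to compare.

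A second hypothesis is that fewer VRTN cells were in S phase. Small nucleolar RNAs, which lack a poly(A) tail, were lower by less, and the histone median minus theirs was -0.089 (95% bootstrap interval over genes -0.14 to -0.036). The bootstrap takes genes as independent and leaves out the spread between arrays, so it does not decide whether such RNAs were lost equally. In the same-numbered pairs the histone medians were -0.19, -0.12 and -0.15, below small nucleolar RNA medians of -0.051, -0.028 and -0.071. The G1/S median of -0.10 lay below 10000 random lists matched on level (central 95% range -0.059 to 0.00096), as fewer cells in S phase would give, but it was -0.063 without VRTN replicate 3. The random lists do not carry the correlation within the G1/S list, whose call was lost at adjusted p = 0.825 with an estimated correlation, and cell cycle phase was not measured, so the hypothesis stays open.

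Chance was weighed by splitting the 6 arrays in all 10 ways. For probe sets, the real split called 4 and the highest other 0, and 1 split, the real one, gave as many. For heat shock members, the real split called 12 and the highest other 0, and 1 split, the real one, gave as many. The heat shock median was 0.22 in the real split and ranged from -0.099 to 0.17 in the others. The other splits mix VRTN and control arrays, so a group difference adds to their spread and lowers their calls. The counts of 0 are thus no measure of how distinct the real split is. For lists, the real split called 10 and the highest other 14, and 5 of the 10 splits, the real one included, gave as many. With 10 splits no share under 0.05 can be had. The 3 other splits that part all 3 pairs called 2, 6 and 11 lists and 0 probe sets, also 0 with the replicate block. With that block they gave at most 1153 probe sets at an unadjusted p under 0.05 against 3357 in the real split, while the remaining 6 splits put same-numbered arrays on one side. One of these, VRTN replicates 1 and 2 with empty vector replicate 1, gave 4360 probe sets at an unadjusted p under 0.05 against 1627 in the real split, which points to the structure by replicate number.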
